A study of Homo sapiens with 2 samples.

How the data were processed

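Circular DNA was measured in 1 Omni-ATAC-seq library each of the cell lines OVCAR8 and C4-2B, from 50000 cells per library, per the labels. The labels name the prostate line C4-2B, while their culture protocol names its parent line C4-2, and the name C4-2B is used here. Reads were aligned with BWA and the build was hg38, per the submitters' processing notes. The circle caller, its version, its filters and the sequencing depth are not given in the sources used here. The deposited values are whole-number junction counts per locus, not scaled to depth, per the file headers (column JT). Each locus also has a chromosome, a start, an end and the bases of a motif at the junction, or a mark for no motif, per the file headers. Coordinates are printed as the authors deposited them. Whether starts count from 0 or from 1 is not given in the sources used here, so that a position may be off by 1 base. Groups were the cell lines, as the labels name them.

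Gene positions came from a RefSeq gene table of the assembly GRCh38.p14, which shares its coordinates with hg38 on the chromosomes. Of 59792 entries in that table, 58961 on the primary chromosomes were used, 19866 of them protein-coding, and 831 on other sequences were left out. The table gives gene bodies without strand, exons or UTRs, so that exonic, intronic and promoter positions were not analysed here. Gene lists took gene bodies with 1 kb on either side. Without a genome sequence, gaps were approximated by the 22 spans over 2 Mb without any gene, and usable length was 2849 Mb on chromosomes 1 to 22 and X. Loci on any other chromosome, 30 in C4-2B, entered the number, length, count and motif results over all loci and the length density. They entered no merged or other alternative set of loci, no counts of loci between 1 kb and 1 Mb, and no placement, chromosome or naming result.

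Numbers of loci have exact 95% Poisson intervals and shares have Wilson intervals. Differences of shares have Newcombe intervals. Medians have bootstrap intervals from 2000 resamples of loci. Maxima of the length density came from a Gaussian kernel with a bandwidth of 20 bp over lengths under 1000 bp, with 1000 resamples. Each chromosome's number of loci was compared with that expected from usable length by a two-sided exact Poisson test with Benjamini-Hochberg adjustment over the chromosomes of a line. Overlaps with genes, gene lists, chromosome ends and loci of the other line were compared with 10000 random placements (1000 for genes touched in both lines, 2000 for alternatives and length subsets, 300 for alternatives of genes touched in both lines) that kept the number, lengths and chromosomes of loci. Correlations over chromosomes were compared with 2000 placements. P-values are two-sided shares of placements as extreme and are called permutation p. They were adjusted by Benjamini-Hochberg over 13 overlap measures and over 12 gene lists per line, at a threshold of 0.05. Loci were called matched when both ends lay within 10 bp. Placements treat loci as independent although many overlap, so that overlapping loci were also merged. Over all lengths, merging also joins short loci into the long loci that span them. It is therefore not a correction for dependence alone.

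Sample groups, tests, gene lists, naming rules and other settings were set before the data were examined. The naming rule took the list genes touched by a locus, up to 20 per line in order of junction count with ties by alphabet, the 5 longest loci, the 5 loci with the highest counts, up to 10 genes with the most loci that do not overlap each other (ties to the shorter gene) and the 10 longest overlaps between the lines. Some genes that the rule names are not reported here. The other settings were placements on any chromosome or within 100 kb, a count above 1, merged loci, loci of 1 kb or less, other definitions of overlap, other distances, other kernel bandwidths, other repeat lengths, expected counts from gene number and gene bodies alone. The ends of protein-coding genes, chromosome ends, placements in gene-free spans, merged short loci, loci without matches in the other line and loci up to 1 Mb were added afterwards. Repeats at the ends, planned from the genome, were taken from the deposited motifs.

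The placement procedure was tested on simulated loci. Of 60 null sets with the lengths of the loci of 1 kb or less, 1 passed the threshold at gene ends for OVCAR8 (228 loci) and 3 for C4-2B (921 loci). With 19 and 81 loci moved onto gene starts, the excess found was 16.4 and 77.8. All 40 planted matches were found in each line. Length maxima planted at 180 and 370 bp were found at 179 and 369 bp for OVCAR8 and at 180 and 369 bp for C4-2B. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.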

Results

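Circular DNA loci were compared between 2 human cancer cell lines, OVCAR8 and C4-2B. OVCAR8 is an ovarian carcinoma line. C4-2B is a prostate cancer line derived from LNCaP cells. Extrachromosomal circular DNA was read from Omni-ATAC-seq libraries, in which a transposase inserts sequencing adapters into accessible DNA and a circle is recognised by reads that cross the junction between its ends. The comparison asked how many circles each line carried, how long they were, where in the genome they came from and which were found in both lines. Each line had 1 library of 50000 cells and no replicates, so no test between the lines as biological samples was possible. Intervals cover counting error over loci, and p-values describe the position of loci within a library against random placements. The sequencing depth of the libraries is not given in the sources used here. Circle stands below for a locus called from junction reads. Whether the loci are circles or other rearrangements of the chromosomes was not tested at any length.

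C4-2B had more circular DNA loci than OVCAR8, mostly loci with a single junction count. In C4-2B there were 1335 loci (exact 95% Poisson interval 1264 to 1409) with 1556 junction counts in total. In OVCAR8 there were 611 loci (interval 564 to 661) with 1316 junction counts. On chromosomes 1 to 22 and X this was 45.8 loci per 100 Mb in C4-2B (43.4 to 48.4) and 21.4 in OVCAR8 (19.8 to 23.2). Most loci rested on a single junction count, 92.1% in C4-2B (95% Wilson interval 90.5 to 93.4) and 85.1% in OVCAR8 (82.1 to 87.7). Some of these were listed next to a locus with a high count and differed from it in length by a few bp. In OVCAR8 loci of 4141, 4142 and 4143 bp stood beside a 4146 bp locus with 176 counts. Whether such loci are the same junction was not tested, so that the number of loci may exceed the number of distinct junctions. Loci with a count above 1 were similar in number, 106 in C4-2B and 91 in OVCAR8. The 10 loci with the highest counts held 38.9% of all counts in OVCAR8 and 5.33% in C4-2B. Because library totals are unknown, the difference in the number of loci was not scaled for depth.

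In OVCAR8 a few loci of intermediate length held many of the junction counts. Loci over 1 kb and up to 1 Mb numbered 250 and held 66.4% of its junction counts, against 287 loci and 21.7% of counts on chromosomes 1 to 22 and X in C4-2B. Of the 12 OVCAR8 loci with a count of 10 or more, 11 were in that length range and held 522 of its 874 counts, which left 352 counts on the other 239 loci (1.47 per locus) and 44.3% of the counts in that range without the 11. Of the 12, 6 held at least 1 complete protein-coding gene. In C4-2B there were 4 loci with such counts and none of them was in that range. The highest count, 176, was at a 4146 bp locus on chromosome 21 (41641805 to 41645951, hg38) that touched no gene and lay 93422 bp from RIPK4, a kinase gene of epidermal differentiation. The next, with 98 counts, was a 4624 bp locus on chromosome 8 (132926653 to 132931277) inside TG, the gene for thyroglobulin. A 409540 bp locus on chromosome 10 (73493290 to 73902830) had 63 counts and held 10 complete protein-coding genes, among them the calcium-signalling kinase gene CAMK2G and SEC24C, which encodes a coat protein of secretory vesicles. A 7514 bp locus on chromosome 1 (169109067 to 169116581) inside ATP1B1, the gene for the beta subunit of the sodium pump, had 44 counts. A 38127 bp locus on chromosome 9 (124475741 to 124513868) had 27 counts and held the complete NR5A1 gene, which encodes a nuclear receptor of steroid-producing tissues. In C4-2B the highest count, 16, was at a 107 bp locus on chromosome 16 (89566206 to 89566313) inside RPL13, which encodes a protein of the large ribosomal subunit. A count of 11 followed at an 839 bp locus outside annotated genes on chromosome 10 (130300872 to 130301711), and a count of 10 at a 644 bp locus in the serotonin receptor gene HTR3B (chromosome 11, 113934810 to 113935454). A 36.6 Mb locus on chromosome 17 (7314901 to 43900458) also had 10 counts. A 229 bp locus in JAG2, which encodes a Notch ligand, had 8 counts (chromosome 14, 105162463 to 105162692). None of these 10 loci had both ends within 10 bp of a locus of the other line.

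**Figure D1:**
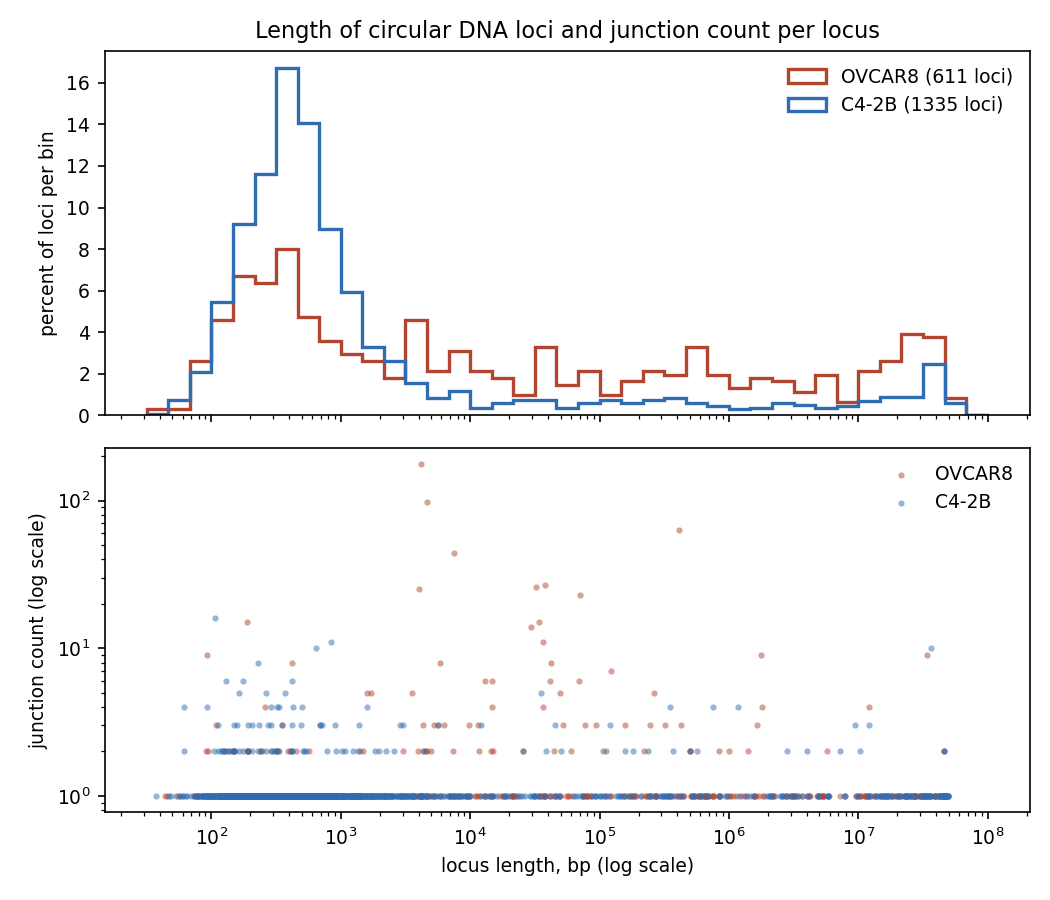
Length of circular DNA loci in bp on a log axis, as percent of loci per bin (top), and junction count per locus on a log axis against length (bottom), with each point 1 locus and each colour 1 line. C4-2B had most loci at or below 1000 bp, while 11 of the 12 OVCAR8 loci with a count of 10 or more lay above that length.

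Loci were much shorter at the median in C4-2B. The median length was 521 bp in C4-2B (bootstrap interval over loci 491 to 564) and 5008 bp in OVCAR8 (3919 to 9803). Loci of 1 kb or less made up 69.1% in C4-2B (66.5 to 71.5) and 37.3% in OVCAR8 (33.6 to 41.2). The OVCAR8 share minus the C4-2B share was -31.7 percentage points (95% Newcombe interval -36.2 to -27.1). The gap lay in the class of over 200 bp to 1 kb, with 53.9% of C4-2B loci and 23.4% of OVCAR8 loci, and not in the shortest class of up to 200 bp, with 15.1% and 13.9% and a difference of -1.22 points (-4.45 to 2.27). Of the 720 C4-2B loci of over 200 bp to 1 kb, 39 had a count above 1, and of the 143 OVCAR8 loci 12. Sequencing depth is not known, and its part in the gap was not tested. Above 1 Mb lay 133 OVCAR8 loci (21.8%) and 109 C4-2B loci (8.16%), a difference of 13.6 points (10.1 to 17.3). Without those loci the OVCAR8 median was 1258 bp, while with a count above 1 it was 9803 bp and without loci matched in C4-2B 8915.5 bp. Among loci under 1000 bp, the density of lengths was highest at 141 bp in OVCAR8 (bootstrap interval 111 to 249) and at 192 bp in C4-2B (125 to 419). Further maxima lay at 248, 319, 423, 560, 631, 739, 808 and 886 bp in OVCAR8 and at 130, 280, 341, 414, 510, 572, 749, 825, 904 and 984 bp in C4-2B. Of these, the one at 423 bp in OVCAR8 and the one at 414 bp in C4-2B came back in the most resamples, 94.9% and 95.8%, and those at 631 bp and 510 bp in the fewest, 63.1% and 50.1%. Resamples took loci as independent, although a region of chromosome 3 (93470362 to 93470788) gave OVCAR8 overlapping loci of 406 to 423 bp matched in C4-2B. No baseline for such recurrence was computed. The wide intervals leave the position of the tallest maximum open.

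The longest loci reached nearly 50 Mb, each on a single junction count. Loci of both lines stopped just below 50 Mb. Whether this is a setting of the caller is not given in the sources used here. In OVCAR8 the 5 longest lay on chromosomes 3, 1, 19, 17 and 1. The longest, 49.1 Mb on chromosome 3 (38165507 to 87260242), held 328 complete protein-coding genes, among them the tumour suppressors BAP1, PBRM1 and SETD2 and the Wnt effector CTNNB1. The chromosome 19 locus of 47.4 Mb (1248678 to 48635999) held 999, among them AKT2 and the cyclin gene CCNE1. The chromosome 17 locus of 47.2 Mb (2451458 to 49694378) held 743, among them BRCA1 and ERBB2. Those of 47.6 Mb and 47.0 Mb on chromosome 1 (65250600 to 112803024 and 115202799 to 162198705) held 250 and 450, the second of them a cluster of histone genes. In C4-2B the 5 longest lay on chromosomes 3, 12, 12, 1 and 12 and measured 47.6 to 49.7 Mb. The longest, on chromosome 3 (130048888 to 179739846), held 215 complete protein-coding genes, among them PIK3CA and MECOM. The others held 462, 265, 286 and 391. The chromosome 12 loci of 49.4 Mb (6873374 to 56258388) and 47.6 Mb (48743549 to 96312084) held the keratin genes KRT8 and KRT18, and the latter also CDK4 and MDM2. All 10 of these loci had a count of 1.

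The junction motifs, the identical bases that the files list for each junction, were about as often absent in both lines. No motif was listed for 56.0% of OVCAR8 loci (52.0 to 59.9) and 56.0% of C4-2B loci (53.3 to 58.6). Motifs of 3 bp or more were present at 57 OVCAR8 loci (9.33%, 7.27 to 11.9) and 128 C4-2B loci (9.59%, 8.12 to 11.3), a difference of -0.259 points (-2.93 to 2.70). With a count above 1, on chromosomes 1 to 22 and X, these shares were 9.89% and 14.7%. Motifs of 2 bp were listed for 7.53% of OVCAR8 loci (5.69 to 9.90) and 10.5% of C4-2B loci (8.96 to 12.2). Motifs of 6 bp or more were listed for 16 and 26 loci. The longest had 14 bases in both lines. Among motifs of a single base, G or C made up 53.0% in OVCAR8 (45.4 to 60.5) and 61.3% in C4-2B (55.8 to 66.4).

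Relative to chromosome length, circular DNA loci were dense on chromosomes 10, 17 and 20 and sparse on chromosomes 4, 18 and X in both lines, and in C4-2B also dense on chromosomes 19 and 22 and sparse on 6 and 13. Of the dense ones, chromosome 10 had 5.62 protein-coding genes per Mb and chromosome 19 had 25.6. In C4-2B chromosome 19 had 73 loci where 25.2 were expected from its length (2.90-fold, Poisson interval 2.27 to 3.64). Chromosome 22 was at 2.55-fold (1.85 to 3.42), chromosome 20 at 2.01-fold (1.52 to 2.60), chromosome 17 at 1.52-fold (1.15 to 1.98) and chromosome 10 at 1.36-fold (1.08 to 1.69). Chromosome X was at 0.318-fold (0.199 to 0.482), chromosome 18 at 0.556-fold, 13 at 0.613-fold, 6 at 0.648-fold and 4 at 0.674-fold. In OVCAR8 chromosome 17 had 35 loci where 16.9 were expected (2.07-fold, 1.44 to 2.88), chromosome 20 was at 1.81-fold (1.16 to 2.69) and chromosome 10 at 1.54-fold (1.11 to 2.07). Chromosome 18 had 2 loci (0.125-fold, 0.0151 to 0.451), X 6 where 32.4 were expected (0.185-fold, 0.0680 to 0.403) and chromosome 4 was at 0.496-fold. These 10 chromosomes in C4-2B and 6 in OVCAR8 passed the exact Poisson test with Benjamini-Hochberg adjustment over 23 chromosomes, the adjusted p ranging up to 0.0230 and 0.0391. The test counts overlapping loci as independent. On chromosome 10 in C4-2B, 9 of the 81 loci lay within 130300525 to 130301916 and 6 within 132364333 to 132364843. The part of such regions in the chromosome 10 fold was not tested. With overlapping loci merged 5 and 2 passed, and with expectation from the number of protein-coding genes 5 and 6 passed. Chromosome 19 did not pass in OVCAR8 (20 loci, 1.69-fold). Expected numbers took no account of DNA copy number or reads per chromosome, so that their part in the chromosome folds was not tested. Loci per Mb rose with protein-coding genes per Mb over the 23 chromosomes, with Spearman rho 0.753 (Pearson r 0.821, placement p = 0.002) in C4-2B and 0.555 (r 0.559, p = 0.0070) in OVCAR8. Chromosomes are not independent replicates. Without chromosomes 19 and 17 rho was 0.683 (r 0.734, p = 0.0030) in C4-2B and 0.425 (r 0.463, p = 0.071) in OVCAR8, no longer past the threshold. With overlapping loci merged, rho was 0.172 in C4-2B and 0.0553 in OVCAR8, past no threshold, whereas with only loci of 1 kb or less merged it was 0.820 (permutation p = 0.001) and 0.50 (permutation p = 0.014). Merging over all lengths took C4-2B from 1305 to 678 loci and OVCAR8 from 611 to 253. Merging only loci of 1 kb or less took C4-2B from 921 to 837 and OVCAR8 from 228 to 194. With a count above 1 the number of chromosomes past the test was 1 and 0, and rho was 0.417 (permutation p = 0.040) and 0.594 (permutation p = 0.0030).

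**Figure D2:**
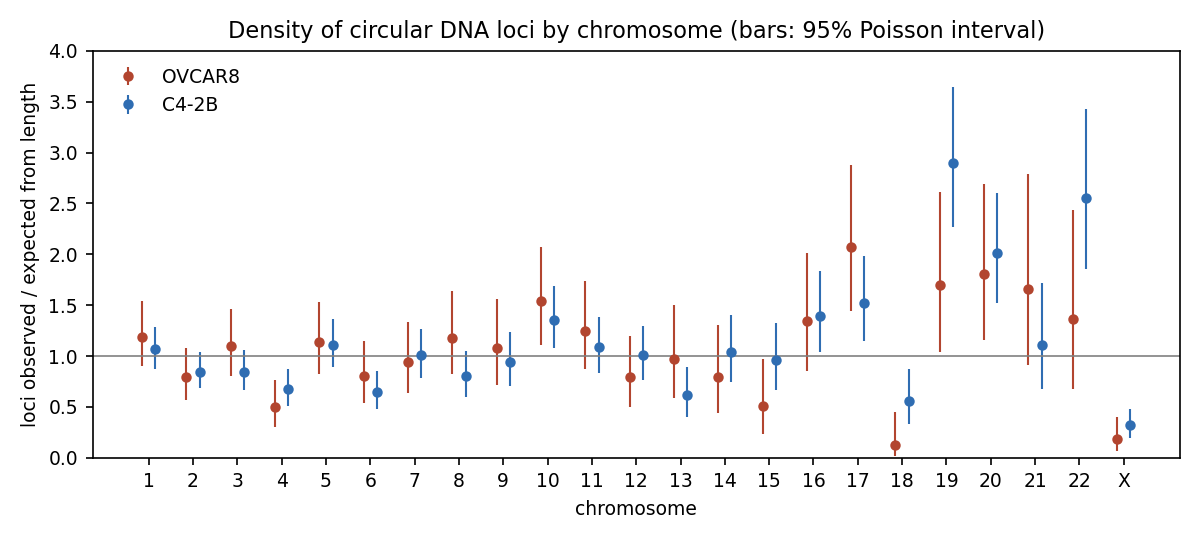
Number of circular DNA loci on each chromosome divided by the number expected from its length, per line, with exact 95% Poisson intervals as bars and the grey line at 1. Chromosome 19 stood at 2.90 in C4-2B, and chromosome X at 0.318 in C4-2B and 0.185 in OVCAR8.

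Loci of both lines touched protein-coding genes more often than placements of the same lengths on the same chromosomes, by a small margin, and as a ratio the excess was larger at the ends of those genes. A protein-coding gene body was touched by 428 of 611 OVCAR8 loci against 387 placed (1.10-fold) and by 761 of 1305 C4-2B loci against 674 placed (1.13-fold), each with a permutation p = 0.0002, the smallest that the 10000 placements can give. The 1 kb on either side of a protein-coding gene end served as a stand-in for promoters that was chosen after the data were seen. It was touched by 269 OVCAR8 loci against 224 placed (1.20-fold) and 240 C4-2B loci against 182 placed (1.32-fold), both at that same p. Long loci that span whole genes count here too, and 197 OVCAR8 and 126 C4-2B loci held a complete protein-coding gene. Among loci of 1 kb or less the excess at gene ends was 4.72-fold in OVCAR8 (35 of 228 loci, 7.41 placed) and 2.45-fold in C4-2B (79 of 921, 32.3 placed), adjusted p 0.00162 and 0.0013. Placements were even along a chromosome and took no account of DNA accessibility or read density. Their part in the excess at genes and gene ends was not tested. Long noncoding RNA genes were touched by 256 OVCAR8 loci against 274 placed (0.935-fold, adjusted permutation p = 0.0404, and 0.078 without loci over 1 Mb, 0.259 for loci of 1 kb or less) and by 310 C4-2B loci against 322 placed (adjusted p = 0.457). Pseudogenes were touched by 201 and 150 loci against 209 and 157 placed (adjusted p 0.207 and 0.435). Any gene body was touched by 77.2% of OVCAR8 loci (adjusted permutation p = 0.574) and 69.8% of C4-2B loci (1.07-fold, adjusted p = 0.000867). When placements stayed within 100 kb of each locus, the protein-coding excess was 1.02-fold in OVCAR8 (permutation p = 0.335) and 1.03-fold in C4-2B (p = 0.051), while the excess at gene ends was 1.10-fold and 1.17-fold (permutation p = 0.001 for both). Among loci with a count above 1 the protein-coding excess was 1.21-fold in OVCAR8 (permutation p = 0.017) and 0.982-fold in C4-2B (permutation p = 0.889).

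Complete protein-coding genes were carried more often than placed in OVCAR8, by 197 loci against 181 (1.09-fold, adjusted permutation p = 0.00182), and were carried by 126 C4-2B loci against 121 placed (adjusted p = 0.370). A difference between the lines in this excess was not tested. Without loci over 1 Mb, 69 OVCAR8 loci carried a complete gene against 50.1 placed (1.38-fold, adjusted permutation p = 0.0013) and 31 C4-2B loci against 25.2 placed (1.23-fold, adjusted permutation p = 0.115). The outer 5 Mb of the chromosomes were touched by many loci in both lines, a measure added after the data were seen. They were touched by 126 OVCAR8 loci against 50.7 placed (2.48-fold) and 325 C4-2B loci against 109 placed (2.99-fold), each with a permutation p = 0.0002. Among loci of 1 kb or less it was 36.0% of OVCAR8 loci (30.0 to 42.4) and 30.2% of C4-2B loci (27.3 to 33.2) against 8.12% and 8.08% of placements. The part of accessibility and read density in this was not tested either.

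**Figure D3:**
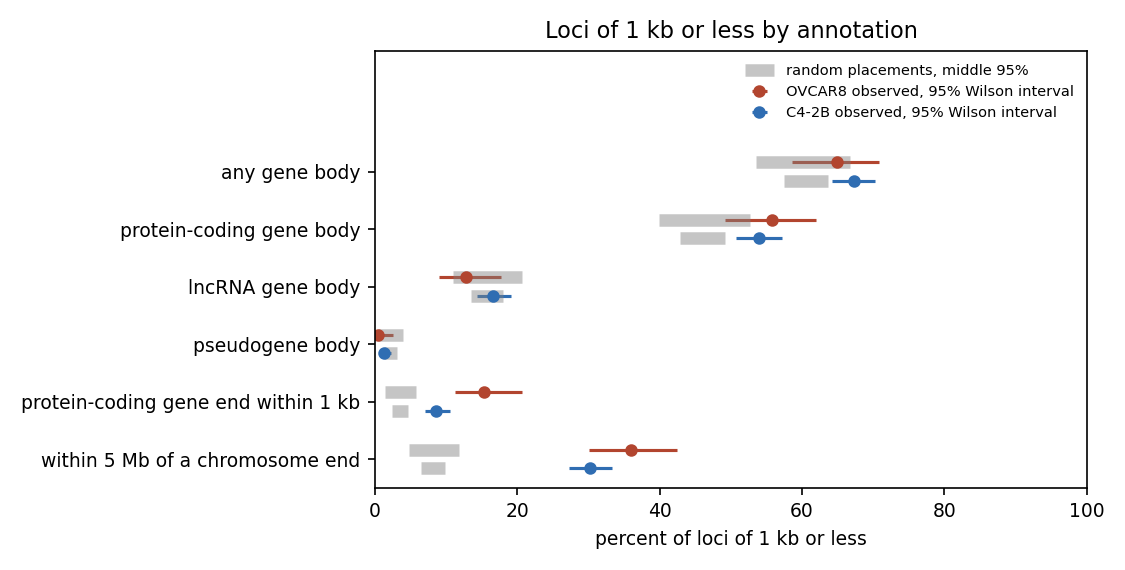
Percent of loci of 1 kb or less that touched each annotation class, as points with 95% Wilson intervals for OVCAR8 and C4-2B, with grey bands for the middle 95% of random placements of the same loci. Ends of protein-coding genes (15.4% and 8.58%) and the outer 5 Mb of chromosomes (36.0% and 30.2%) lay above the placements in both lines. The placements took no account of accessibility or read density.

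None of the 12 gene lists was touched more or less often than placements in either line after Benjamini-Hochberg adjustment over the lists. At an unadjusted p under 0.05 there were 3 lists in OVCAR8 and 0 in C4-2B. Histone genes were touched by 12 OVCAR8 loci against 5.92 placed (adjusted permutation p = 0.156), the long fragile-site genes by 14 against 22.3 and the fibroblast and endothelial markers by 7 against 13.4 (adjusted p = 0.192 for both). Oncogenes were touched by 27 loci in OVCAR8 (28.3 placed) and 19 in C4-2B (21.7 placed), and tumour suppressors by 20 in each (18.4 placed in each). Prostate and androgen-response genes were touched by 29 loci in OVCAR8 (23.6 placed) and 19 in C4-2B (21.3 placed), and ovarian and Mullerian genes by 21 (19.8 placed) and 18 (16.5 placed). The counts for C4-2B were 36 for ribosomal protein genes (37.0 placed), 3 for histone genes (5.13), 25 for DNA repair genes (20.2), 18 for fragile-site genes (25.9), 10 for blood cell markers (14.2), 13 for fibroblast and endothelial markers (13.9), 18 for olfactory receptors (21.8) and 17 for neuronal synaptic genes (15.4). The remaining OVCAR8 counts were 47 for ribosomal protein genes (45.3 placed), 21 for DNA repair genes (24.3), 15 for blood cell markers (15.0), 21 for olfactory receptors (21.6) and 15 for neuronal synaptic genes (15.7).

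Most list genes were reached only by very long loci. Of 34 oncogenes, 19 were touched in OVCAR8 and 17 in C4-2B, but by loci of up to 1 Mb only 0 and 2. Ranked by junction count, the leading list genes in OVCAR8 were the oncogene MYC and the androgen-responsive gene NDRG1, both within a 33999503 bp locus on chromosome 8 (106950568 to 140950071) with 9 counts. NHEJ1, an end-joining factor, lay in a 12143256 bp chromosome 2 locus (217924298 to 230067554) with 4 counts. This locus was matched in C4-2B, with 3 counts there, and a motif made of a dinucleotide repeat was listed for it. EP300, a histone acetyltransferase gene, was touched by a 77677 bp locus with 3 counts (chromosome 22, 41022258 to 41099935). FHIT, at a common fragile site, was touched by a 993687 bp locus with 2 counts (chromosome 3, 59160655 to 60154342). FOXA1, RPL10L and RPS29 shared a chromosome 14 locus with 2 counts. ACP3, ACTA2, AKT2, AMACR, AMHR2, APC, ARID1A, ATM, BAP1, BRCA1, CCND1 and CCNE1 followed at a count of 1. In C4-2B RPL13 led with its 16 counts. The 36.6 Mb chromosome 17 locus with 10 counts held, among others, BRCA1, NF1, CDK12, ERBB2, LHX1, LIG3, CD68 and the ribosomal genes RPL19, RPL23, RPL23A, RPL26 and RPL27. NHEJ1, in the matched chromosome 2 locus, and PARP1 and the histone genes H2AC25 and H2BC26 were in loci with 3 counts and ACTA2 in one with 2. Among loci of up to 1 Mb, named here after their values were seen and each with a count of 1, OVCAR8 had among others a 4861 bp locus in the tumour suppressor RB1 (chromosome 13, 48456179 to 48461040). C4-2B had among others a 558 bp locus in the prostate transcription factor gene HOXB13 (chromosome 17, 48726439 to 48726997), a 103006 bp locus with the kallikrein genes KLK2 and KLK3 (chromosome 19, 50783681 to 50886687) and a 208119 bp locus with KRT8 and KRT18 (chromosome 12, 52864752 to 53072871). Without loci over 1 Mb, the prostate and androgen-response list was touched by 4 C4-2B loci against 0.970 placed (adjusted permutation p = 0.480). In the same way fragile-site genes were touched by 8 C4-2B loci against 13.6 placed (adjusted permutation p = 0.752), neuronal synaptic genes by 4 against 4.32 and DNA repair genes by 3 against 1.53 (adjusted p = 1 for both).

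Few genes were touched by several loci that did not overlap each other. In C4-2B there were 43 such protein-coding genes. ZFPM1, which encodes a cofactor of GATA factors, EEFSEC, which encodes the selenocysteine elongation factor, and the cadherin gene CDH4 had 4 loci each. BCR, TNS1, HDAC4, TRAPPC9, RGS6, NTM and CAMTA1 had 3 each. In OVCAR8 there were 9. ADARB2, of the RNA-editing enzyme family, had 3 and the others, TCHH, SPATC1, PTK2, JMJD1C, DST, MAST4, CDH4 and PTPRG, had 2. CDH4 was in both sets. No test of these counts against gene length was run.

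Some circular DNA loci were found at the same positions in both lines. Of the 611 OVCAR8 loci, 53 (8.67%, 6.69 to 11.2) had both ends within 10 bp of a C4-2B locus, and 54 of 1305 C4-2B loci (4.14%, 3.19 to 5.36) had both within 10 bp of an OVCAR8 locus. None of the 10000 placements gave such a locus in either line, with a permutation p = 0.0002, the smallest that can be given. Of the 53, 34 had identical ends and the same motif, and 44 were of 1 kb or less. They included a 716 bp locus in PTPN3 (chromosome 9, 109523566 to 109524282), a 537 bp locus in the cell-cycle transcription factor gene MYBL2 (chromosome 20, 43696475 to 43697012) and a 92 bp locus in PCID2 (chromosome 13, 113176451 to 113176543) with 9 counts in OVCAR8 and 4 in C4-2B. A 499223 bp locus on chromosome 7 (76498794 to 76998017) with DTX2, UPK3B, SPDYE16 and POMZP3 had 2 counts in each line, and 3 matched loci were over 1 Mb. Many matched loci fell into a few short regions where loci overlapped each other. Inside COL23A1, a collagen gene, C4-2B had 18 loci within chromosome 5 positions 178585408 to 178585741 and OVCAR8 had 9. On chromosome 3 (93470362 to 93470788), outside annotated genes, C4-2B had 7 and OVCAR8 11. Merging overlapping loci of 1 kb or less left 28 matched of 194 in OVCAR8. These matched loci were named after their values were seen.

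**Figure D4:**
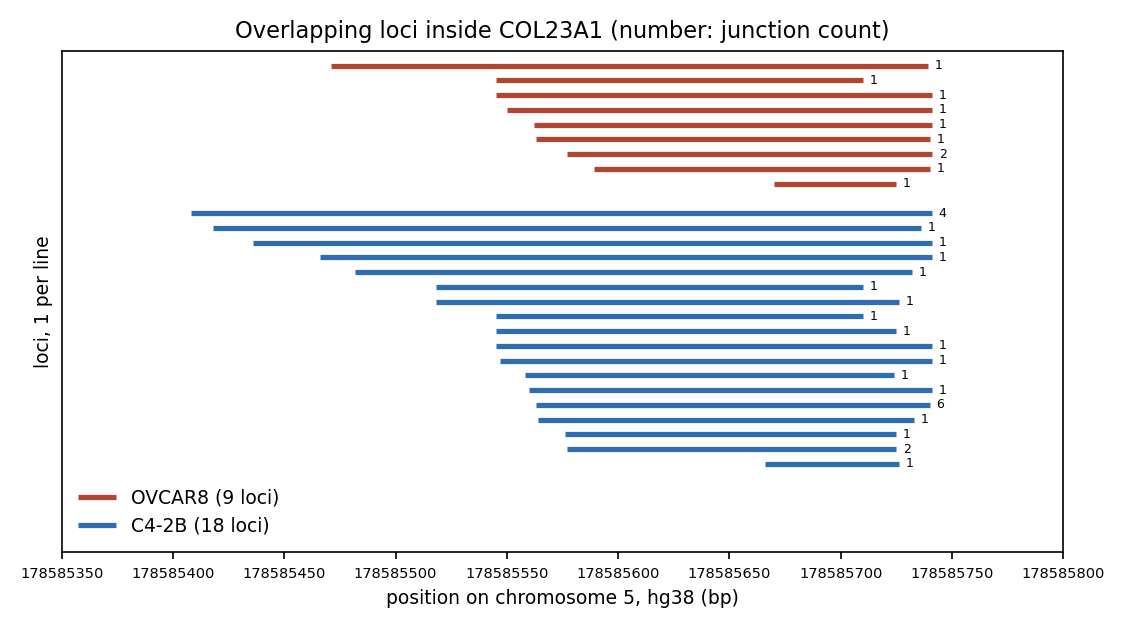
Map of circular DNA loci inside COL23A1 on chromosome 5 (position in bp, hg38), with each horizontal line 1 locus, the number beside it its junction count, and colours for the lines. Of the 9 OVCAR8 loci, 7 had both ends within 10 bp of 1 of the 18 C4-2B loci and 3 of them had identical ends.

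Counted by simple contact, 405 OVCAR8 loci (66.3%) touched a C4-2B locus against 357 placed (1.13-fold, permutation p = 0.0002), and 759 C4-2B loci (58.2%) touched an OVCAR8 locus against 753 placed (1.01-fold, p = 0.698). Within 10 kb it was 414 against 360 placed and 768 against 755 placed (permutation p = 0.0002 and 0.401). The very long loci set these values. The 10 longest overlaps between the lines measured 32.7 to 46.1 Mb and each held between 106 and 752 complete protein-coding genes. The longest of them was a 46.1 Mb locus with the same ends in both lines (chromosome 16, 28915161 to 75019848). Among loci of 1 kb or less, 65 of 228 OVCAR8 loci touched a C4-2B locus against 0.056 placed, and 83 of 921 C4-2B loci touched an OVCAR8 locus against 0.058 placed. With overlapping loci merged, which joins short loci into long ones that span them, the C4-2B value over all lengths was 0.892-fold. Protein-coding genes touched in both lines numbered 7008 of 11146 in OVCAR8 and 10128 in C4-2B, against 6532 placed (1.07-fold, permutation p = 0.326). For loci of 1 kb or less the number was 26 against 10.4 placed (2.49-fold, permutation p = 0.0133), and without loci over 1 Mb it was 66 against 35.9 placed (1.84-fold, p = 0.0133). Genes at matched loci, such as PTPN3, MYBL2 and PCID2, count here too. These excesses are therefore not separate from the matched loci, and at these lengths they were not tested without them.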

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

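The alternatives with merged loci of 1 kb or less, without matched loci, without loci over 1 Mb and with gene-free spans were chosen after the data were seen. Over 33 results and 275 alternatives, 209 kept their side of the threshold or moved within their error, and 4 reversed with the main or the alternative value past the threshold. A change of direction with neither value past the threshold counted as kept. Small changes in the number of chromosomes past the test also counted as kept. No paired analysis was possible because each line has 1 library and the lines share only the replicate number 1. Not run for want of a genome sequence, strand or exons were GC content, the CpG ratio, repeat-masked share, GC-matched placements, the other reading of the start, promoters, UTRs and exons. Counts of 1 at most loci and the unknown depth limit every value. The cause of a change was not tested unless given.

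The number of loci on chromosomes 1 to 22 and X changed with each subset by construction, in OVCAR8 to 91 with a count above 1, 253 merged, 228 of 1 kb or less, 194 of those merged, 558 without matches and 478 without loci over 1 Mb, and in C4-2B to 102, 678, 921, 837, 1251 and 1208. The median length in OVCAR8 was 266 bp for loci of 1 kb or less, 289.5 bp for those merged and 1258 bp without loci over 1 Mb, and within its interval 9803 bp with a count above 1 and 8915.5 bp without matches. In C4-2B it was 424.5 bp with a count above 1, 359 bp, 383 bp and 460 bp. The share of 1 kb or less in OVCAR8 was 26.4% with a count above 1, 33.0% without matches and 47.7% without loci over 1 Mb. In C4-2B it was 63.7% with a count above 1, 72.6% merged and 76.2% without loci over 1 Mb. Motifs of 2 bp or more made up 16.9% and 20.1%, those of 10 bp or more 1.31% and 0.899%, those of 3 bp or more 12.3% of short OVCAR8 loci and 14.7% of C4-2B loci with a count above 1.

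Chromosomes past the threshold in OVCAR8 were 0 with a count above 1, 2 merged and 3 for merged short loci. In C4-2B they were 5 with expectation from gene number, 1 with a count above 1, 5 merged and 6 for merged short loci. The Spearman correlation with gene density was 0.0553 and 0.172 with loci of all lengths merged, but 0.50 and 0.820, past the threshold, with merged loci of 1 kb or less. Protein-coding gene overlap was 1.02-fold and 1.03-fold for placements within 100 kb, no longer past the threshold. In C4-2B with a count above 1 it was 0.982-fold (permutation p = 0.889), and any gene body 0.967-fold (p = 0.692), both reversed but not past the threshold. Any gene body in OVCAR8 was 1.04-fold with placements in gene-free spans (permutation p = 0.044).

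C4-2B loci touching OVCAR8 loci, and those within 10 kb, passed at 1.07-fold and 1.08-fold for placements on any chromosome, 1.12-fold and 1.11-fold within 100 kb, 4.44-fold and 4.62-fold with a count above 1, 1431-fold and 62.1-fold for loci of 1 kb or less, 759-fold and 36.1-fold for those merged, and 8.28-fold and 7.56-fold without loci over 1 Mb. Touching with at least 50% of both loci covered was 4.05-fold. Merged over all lengths, where short loci within long ones no longer count on their own, they reversed to 0.892-fold and 0.912-fold, both past the threshold. OVCAR8 loci touching C4-2B loci, and those within 10 kb, were 7.27-fold and 6.46-fold without loci over 1 Mb. For loci of 1 kb or less the OVCAR8 values were 1161-fold and 47.0-fold. Genes touched in both lines passed at 1.32-fold for placements on any chromosome, 14.9-fold with a count above 1, 1.30-fold merged, 2.49-fold for loci of 1 kb or less, 3.17-fold for those merged and 1.84-fold without loci over 1 Mb. Genes at matched loci count in these values.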

Other observations

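The tests of carry-over from OVCAR8, of clustering of short loci and of chance identity of junction bases were chosen only after the results were seen, as were the regions and motifs described here, and the test of random joining was changed after its result was seen, to keep random ends out of gene-free spans, with the observed medians below the range in either form.

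Some short loci overlapped each other. In OVCAR8 49 of 228 loci of 1 kb or less (21.5%) and in C4-2B 122 of 921 (13.2%) overlapped another such locus of the same line, against 0.008 and 0.254 on average in 1000 random placements. Of the 15 and 38 clusters, 11 and 26 held 2 loci. Beside COL23A1, a region outside protein-coding genes on chromosome 10 (130300525 to 130301916) had 9 loci in C4-2B with 21 counts and 0 in OVCAR8, and a region in ADARB2 (chromosome 10, 1327135 to 1328008) had 4 loci in OVCAR8 and 0 in C4-2B. In JAG2 (chromosome 14, 105162457 to 105162692) C4-2B had 3 loci with 12 counts. Some junctions carried simple repeats. Motifs with the 5 bp unit GGAAT of classical satellite DNA, in any frame or strand, were listed for 3 OVCAR8 and 11 C4-2B loci, of which 2 and 8 lay within 2 Mb of a gene-free span. Motifs made of a dinucleotide repeat were listed for 7 and 15 loci.

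Loci with both ends matched in the other line were found 53 times in OVCAR8. If fragments of OVCAR8 had been carried into the C4-2B library, its loci with the highest counts would have been matched most often, at 82.9% for counts of 10 or more from the rate at a count of 1. Of those, 1 of 12 was matched, 8.33% (exact 95% interval 0.211 to 38.5), which argues against it as the whole cause. Carry-over from C4-2B cannot be told apart from other sources, since 3 of 12 loci with a count of 5 or more were matched, 25% (5.49 to 57.2) against 18.0% expected. Matched loci lay in clusters of overlapping loci more often than others, with an odds ratio of 3.90 in OVCAR8 (19 of 44 against 30 of 184, Fisher's exact p = 0.000336) and 10.0 in C4-2B. Sites prone to junction reads in any library may account for part of them, although a cluster also gives more chances of a match. The repeat content of these sites was not measured. The cell lines themselves, including circles formed at the same sites, remain untested.

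Loci over 1 Mb numbered 133 in OVCAR8 and 97 on chromosomes 1 to 22 and X in C4-2B. If unrelated positions drawn evenly along a chromosome had been joined, over 1 and up to 50 Mb apart, medians would have been 18.3 to 26.2 Mb and 17.3 to 26.5 Mb. The observed medians were 15.1 Mb in OVCAR8 and 16.9 Mb in C4-2B, below both ranges but only narrowly in C4-2B. This argues against evenly drawn joining alone, if the caller has no preference for length and loci are independent, although some overlap. Joining that favours nearby positions was not simulated, so that the test cannot decide on it. Genes of a shared name root stood within 10 kb of both ends at 2 loci in each line (PKD1 and its pseudogene PKD1P5 on chromosome 16 in OVCAR8, GGT1 and GGT3P on chromosome 22 in C4-2B among them), where re-paired ends gave 0.966 and 1.03 on average, so that reads shared between gene copies cannot be told apart from other causes at these numbers. Whether these loci are circles or other rearrangements of the chromosomes of either line was not tested.

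The share of junctions without a motif, 56.0% in both lines, was close to the 56.2% that chance identity of bases at the ends gives in equal base composition. The shorter motifs did not all follow chance. Motifs of 1 bp made up 24.0% in C4-2B (21.8 to 26.3) against 28.1% to 28.3% from chance (two-sided exact binomial p = 0.00259, adjusted over 4 comparisons), whereas in OVCAR8 they made up 27.2% (adjusted p = 1), and motifs of 2 bp made up 7.53% in OVCAR8 (adjusted p = 0.0584) and 10.5% in C4-2B (adjusted p = 1) against 10.5% to 10.8%. Motifs of 3 bp or more exceeded chance. They were listed at 9.33% and 9.59% of loci, with lower limits of 7.27% and 8.12%, against at most 5.29% from chance over the base compositions tried. Chance in evenly mixed bases thus does not account for the motif lengths as a whole, and whether repeats or the joining of ends account for them was not tested. No difference between the lines was detectable in this share.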
